A study of Zea mays
Aspergillus flavus with 112 samples.

How the data were processed

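Kernels of the maize inbred line B73 were inoculated in the field with Aspergillus flavus, an ear-rot mould that can make aflatoxin, and sampled over 14 time points. Per the labels' protocols, ears at the milk stage were wounded and inoculated with a bar of pins carrying conidia, 8 plots served as replicates, 1 ear was taken per plot and time point, and 8 kernels of that ear were ground together. Each time point therefore had 8 libraries, 112 in all, and the libraries taken at 0h are the only group that the labels call control. The replicate number in the labels is the plot number, so libraries of 1 number came from different ears of the same plot. The labels give the sampling times in 3 places that do not match in full, and the time in each sample's own label was used. Wounding, fungal growth, kernel development and hour of the day all changed along the series, and no uninoculated kernels of matched times were analysed here, so every difference below is a difference between times.

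The deposited tables held, per library, whole-number read counts for 52958 features, of which 39469 were maize and 13489 were A. flavus genes. Per the labels, total RNA was made into strand-specific libraries, and each deposited table lists the genes of both organisms. Whether counting used the strand is not stated. The counts were used as deposited by the authors. The column of total reads per gene, which includes reads placed at more than 1 site, was the main measure and the column of uniquely placed reads was an alternative. Columns for exon reads were 0 in all 112 tables, and the RPKM values the authors deposited were above 0 in only 11 tables, so neither was used. The aligner, the genome builds and the annotations are not given in the sources used here. Coordinates are printed as the tables give them, with the build not stated. Because the way reads were split between near-identical copies is not stated, values of multigene families such as the zeins are uncertain gene by gene, and antisense or overlapping genes could share reads.

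Library depth ranged from 10696902 to 42103418 counted reads. The share of reads placed uniquely ranged from 66.2% to 96.5%. One maize feature, GRMZM2G006937 (chromosome 5, 78289215 to 78344551), took between 7.22% and 67.0% of the maize reads of a library, which lowers the effective depth of the rest. A share of a single library is given with its 95% Wilson interval. A count of 0 allows a share of up to 7.13e-06% to 2.80e-05% of a library's reads, by the rule of 3 counts. Such intervals and limits cover counting error only, since the reads carry no molecular identifiers.

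Maize names came from a RefSeq gene table of another assembly (Zm-B73-REFERENCE-NAM-5.0), used for names only. Of the 39469 maize features 18441 (46.7%) matched it and 2735 had an informative name. The pattern that removed uninformative names was written after the name table had been seen. Gene names for the fungus were not used here, so fungal genes are given as counts, at most 2 identifiers that rose and 2 that fell, and the aflatoxin gene cluster, which was fixed beforehand as the 30 genes between AFLA_139140 and AFLA_139440. Of the other fungal lists fixed beforehand, 8 had 0 members for want of names and gave no result.

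The fungal share was the percentage of all counted reads that fell on A. flavus genes. Each time was compared with 0h by an exact two-sided permutation test of the difference in mean log2(share + 0.000426), with the offset in percent, over all 12870 splits of 16 libraries, and the 13 p-values were adjusted by the Benjamini-Hochberg method. Maize counts were compared by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors computed on maize genes, edgeR's filter on low counts and the 2 compared groups in the fit. Fungal counts were treated in the same way on fungal genes. A fungal time was eligible when at least 6 of its 8 libraries held 20000 or more fungal reads, which made 36h the first eligible time. Genes with an adjusted p under 0.05 were called. Maize genes that varied over the whole course were tested by an F test of the 13 time coefficients in 1 fit of all 112 libraries. Normalised values in CPM, counts scaled to the effective library size, were computed here within each comparison, so the 0h value of a gene differs slightly between comparisons.

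Gene lists were fixed before the data were examined and filled by matching symbols and synonyms, since the name table holds no product text. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. A list with fewer than 5 tested members was not tested. The genes named were, in the main comparisons, the 6 largest rises and 6 largest falls among called genes that moved the same way in all 8 plots and had a mean of at least 5 CPM in the higher group and an informative name, and up to 4 called members of each list by size of change. Which of these stand in the text as examples was decided after their values were seen. Several symbols are ambiguous. TPS can mean terpene synthase or trehalose-phosphate synthase, the feature HB carries the alias GLB1 and may be a haemoglobin, and the symbol MRP1 on GRMZM2G113203 may not be the transfer-cell regulator of that name. The list of cytosolic ribosomal proteins also caught organelle copies. The list of protease inhibitors caught only symbols of ribosome-inactivating proteins, so no protease inhibitor is known to be in it. GRMZM2G085678 matched the pathogenesis-related list as WIN1 and the ethylene list as EREB46, and counts in both, as bz2 does for flavonoids and glutathione S-transferases and INCW2 for transfer layer markers and invertases.

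The tests were tried on simulated counts with 200 changed genes per comparison, and percentages refer to those that passed the filter. For 24h against 0h, over 23376 genes, 96.9% of the genes changed 4-fold and 76.7% of those changed 2-fold were recovered, with 5.98% false calls. For 4h against 0h, over 23361 genes, 94.4% and 59.1% were recovered, with 1.27% false calls. For the fungal comparison of 6d with 36h, over 7583 genes, 58.8% of 85 and 6.73% of 104 were recovered, with 5.00% false calls, so most 2-fold changes there would be missed. For the fungal comparison of 6d with 3d, over 8842 genes, 55.4% and 19.3% were recovered, with 8.14% false calls.

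The plots pair the libraries by the labels. Deviations of libraries of the same plot from their group means correlated by 0.0276 on average over 728 pairs, against -0.00167 for libraries of different plots, and 11 of the 104 pairs that include a 0h library exceeded 0.1. The fit with plot as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Other alternatives were DESeq2 1.42.0, its median-ratio size factors in edgeR, library totals without TMM factors, no filter, a filter of 1 CPM in 8 libraries, all 112 libraries in 1 fit, uniquely placed reads, a 2-fold minimum, and all plots but plot 7, whose early and late libraries carry sample indices of different series. Alternatives chosen after the data were seen left out GRMZM2G006937, the library labelled 4h of plot 4, or the 8 libraries with fewer than 23000 maize genes detected. Lanes differed between the libraries of 0h to 30h and those of 36h to 6d within each plot, so lane and time cannot be told apart between these spans.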

Results

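Transcripts of maize kernels and of the fungus growing in them were measured together by RNA sequencing at 14 times after pin-bar inoculation with A. flavus, from 0h to 6d, in 8 libraries per time. The study set out to follow both partners of the interaction in the same samples. Each library was counted over 39469 maize and 13489 fungal genes, at a depth of 10696902 to 42103418 reads. As libraries of 1 time came from ears of 8 separate plots, p-values measure the spread between plots and ears.

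The first question was how much fungal RNA the kernels held at each time. Fungal RNA stayed near the level of 0h through 12h, was above it from 18h on, and made up 40.1% ± 13.4 (SD, n = 8) of all counted reads at 6d. At 0h, the background, A. flavus genes took 0.00766% ± 0.00512 of the reads. The mean share was 0.0528% ± 0.0505 at 18h, 0.0560% ± 0.0744 at 24h and 0.105% ± 0.0955 at 30h. Plot 7 raised the mean at 24h (0.238%, others at most 0.0492%), and the medians were 0.0349% at 18h and 0.0298% at 24h. The mean was 0.383% ± 0.430 at 36h, 1.39% ± 1.11 at 42h and 1.41% ± 1.89 at 48h (n = 8 each). Plot 8 raised the mean at 48h (5.95%, others at most 1.39%), and the medians were 1.18% at 42h and 0.963% at 48h. Later means were 4.41% ± 2.74 at 3d, 9.26% ± 3.64 at 4d and 22.6% ± 11.7 at 5d.

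Against 0h, the log2 difference was 2.07 at 18h (exact permutation test, adjusted p = 0.0277, higher in 6 of 8 plots), 2.42 at 24h (exact adjusted p = 0.000505, 8 of 8 plots) and 3.24 at 30h (exact adjusted p = 0.00157, 7 of 8 plots). From 36h to 6d each time gave p = 0.000155, the smallest p the splits can give (exact test, adjusted p = 0.000289), with 8 of 8 plots higher. The log2 difference was 4.85 at 36h and 12.40 at 6d. The share at 12h was 0.00749% ± 0.00466, with no call against 0h (log2 difference -0.04, exact adjusted p = 0.929). At 6h the share was 0.00363% ± 0.00366 and lay below 0h by the test on the log scale (log2 difference -1.19, exact adjusted p = 0.0476, higher in 2 of 8 plots). It did not by the test of untransformed shares (difference -0.00403 percentage points, exact adjusted p = 0.103). The mean of 1.57% ± 4.42 at 4h rested on the library labelled 4h of plot 4, which held 12.5% (95% Wilson interval 12.5% to 12.5%) fungal reads. Without it the 4h mean was 0.00581% ± 0.00411 (n = 7) and the log2 difference from 0h changed from 0.97 (exact adjusted p = 0.872) to -0.44 (exact adjusted p = 0.423).

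**Figure D1:**
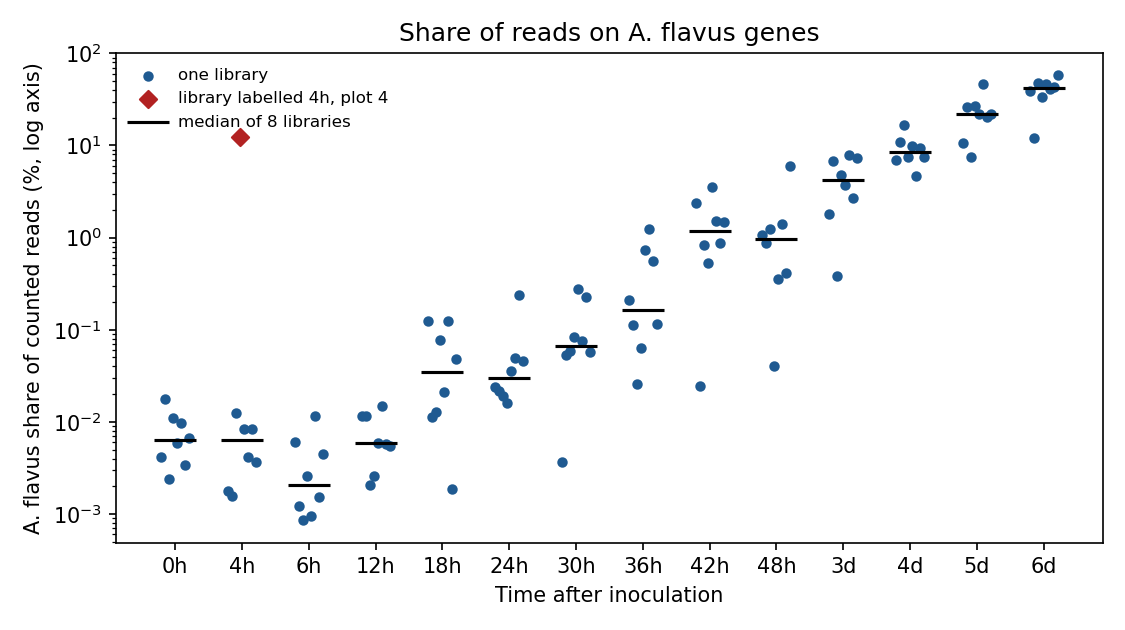
Share of counted reads that fell on A. flavus genes (percent, log axis) against time after inoculation, with 1 point per library, the library labelled 4h of plot 4 as a red diamond and a bar at each median of 8 libraries. All 8 libraries of each time from 36h on lay above the highest 0h library.

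Over the whole course 14108 of 28815 maize genes varied with time (F test of edgeR's quasi-likelihood fit, adjusted p under 0.05). Against 0h, 217 maize genes were called at 4h (189 higher, 28 lower), 568 at 6h (381 higher, 187 lower), 2008 at 12h (1006 higher, 1002 lower) and 2144 at 18h (1142 higher, 1002 lower). Counts were 1260 at 24h (800 higher, 460 lower), 1436 at 30h (914 higher, 522 lower), 3779 at 36h (1930 higher, 1849 lower), 3110 at 42h (1880 higher, 1230 lower) and 1304 at 48h (1043 higher, 261 lower). They reached 2940 at 3d (1845 higher, 1095 lower), 4683 at 4d (2721 higher, 1962 lower), 10678 at 5d (5626 higher, 5052 lower) and 13926 of 23068 tested genes at 6d (7342 higher, 6584 lower).

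With plot as a block the counts were 92 at 4h (75 higher, 17 lower), 883 at 30h (569 higher, 314 lower), 693 at 48h (567 higher, 126 lower) and 1855 at 3d (1119 higher, 736 lower). Without the libraries of low complexity, those with fewer than 23000 maize genes detected, there were 3411 calls at 42h (2027 higher, 1384 lower), 1727 at 48h (1130 higher, 597 lower), 3500 at 3d (2133 higher, 1367 lower) and 6073 at 4d (3308 higher, 2765 lower), of which 2685, 1007, 2781 and 4432 were among the calls above. The share of higher genes among the calls at 48h went from 80.0% to 65.4%. The balance of rises and falls depended on the scaling too. With library totals in place of TMM factors the median log2 change of all genes moved to -0.15 at 6h, -0.21 at 24h, -0.32 at 30h, -0.27 at 36h, -0.19 at 42h and -0.27 at 48h. It moved to -0.31 at 3d, -0.21 at 4d, 0.29 at 5d and 0.74 at 6d. The calls were then 154 higher and 259 lower at 6h, 232 and 350 at 24h, 264 and 505 at 30h, 761 and 3004 at 36h, and 809 and 863 at 42h. Later they were 1041 and 2230 at 3d, 1680 and 2711 at 4d, 6227 and 2760 at 5d, and 11998 and 2818 at 6d. A single fit of all libraries turned the balance the other way at the late times, with 2570 higher and 2746 lower at 4d, 3488 and 4279 at 5d and 4563 and 6155 at 6d, and it gave 482 and 3 at 4h and 265 and 62 at 24h. So neither direction prevails at 4d to 6d under every method. Without plot 7 there were 102 higher and 18 lower at 4h, 303 and 269 at 6h, 563 and 254 at 24h, 1273 and 818 at 30h and 882 and 139 at 48h. The feature GRMZM2G006937 counts in the library totals, and its mean share of maize reads changed with time. It was 25.8% at 0h, 39.4% at 30h and 39.2% at 3d, where library totals moved the median down. It was 18.1% at 6d, where the median moved up. The share did not track every shift, being 32.8% at 18h with a median of 0.008 and 25.6% at 5d with 0.29. Library totals without this feature were not tried, so its part in these shifts was not tested. Directions below are relative to the TMM scale.

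**Figure D2:**
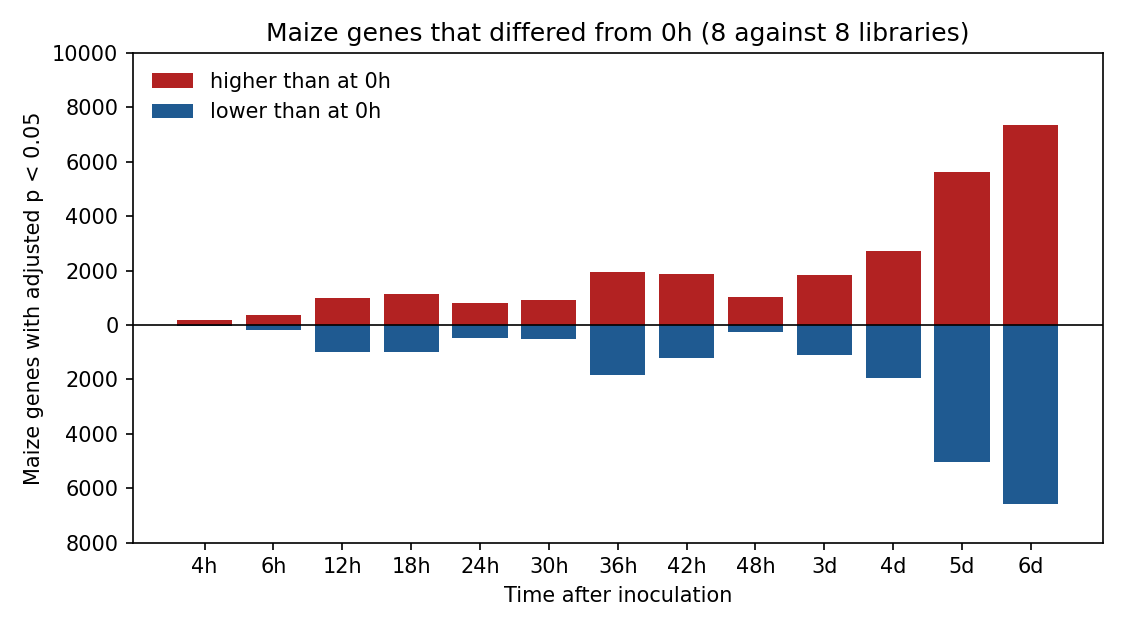
Number of maize genes with an adjusted p under 0.05 against 0h at each of 13 times (8 against 8 libraries, edgeR), with genes that were higher drawn upwards and genes that were lower downwards. The count ran from 217 at 4h to 13926 at 6d and was not monotonic, with 3779 at 36h and 1304 at 48h.

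At 4h, before fungal RNA was above its 0h level in the other plots, the kernels had raised genes of oxylipin and jasmonate synthesis. The lipoxygenase gene lox1 (GRMZM2G156861, chromosome 3, 168738873 to 168882335) went from 48.7 ± 9.35 to 194 ± 72.6 CPM (SD, n = 8), a log2 change of 2.00 ± 0.22 (SE, adjusted p = 3.74e-05, 8 of 8 plots). Changes of genes with ± are log2 changes with their SE throughout. This SE is approximate, computed as the size of the log2 change over the square root of the test's F statistic. The gene for allene oxide synthase, aos1 (GRMZM2G067225), which makes the first committed precursor of jasmonate, rose by 1.38 ± 0.14 (adjusted p = 1.64e-05). The lipoxygenase gene lox10 (GRMZM2G015419) rose by 1.65 ± 0.20 (adjusted p = 8.71e-05). The gene for a ribosome-inactivating protein, rip2 (GRMZM2G119705), rose from 0.730 ± 0.662 to 15.8 ± 5.73 CPM (log2 change 4.45 ± 0.44, adjusted p = 1.05e-05). The ethylene-response factor gene EREB36 fell, with a log2 change of -2.73 ± 0.40 (adjusted p = 0.000775), as did EREB56 (-2.43 ± 0.47, adjusted p = 0.0103).

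Of 23 tested genes of lipoxygenases and jasmonate synthesis 5 rose and 0 fell at 4h (8 rose when adjusted over the list alone; camera adjusted p = 7.89e-10, and adjusted p = 0.0217 with an estimated correlation). This list was filled by symbol. Its members are called jasmonate synthesis genes below for short, though their roles were not tested. No other list held with an estimated correlation. The preset assumes a correlation of 0.01 between members. Other splits of the same libraries called as many lists with it at 4h, and more often at 24h, 3d and 6d, so the p with an estimated correlation is the safer one. Of 20 heat shock genes 1 rose (Hsf26; 4 when adjusted over the list alone) with a median log2 change of 0.37 (camera adjusted p = 4.06e-08, adjusted p = 0.264 with an estimated correlation). Among the largest rises of genes with an informative name were gst24 (GRMZM2G032856), a glutathione S-transferase gene, and aox3, an alternative oxidase gene. Others were lac3, a laccase gene, and BX14, a benzoxazinoid O-methyltransferase gene. The library of plot 4 weighed on these 4. Their log2 changes of 6.76, 5.02, 4.42 and 3.83 became 3.47, 3.33, 2.87 and 3.03 without it, all still called. Without it there were 245 calls (192 higher, 53 lower), 187 of them among the 217. The genes gst7 (log2 change 8.25, then 2.21, adjusted p = 0.449), TPS6 (5.15, then 1.21, adjusted p = 0.175) and CNR2 (3.70, then 1.72, adjusted p = 0.0636) were no longer called. With plot as a block the calls of Hsf26, opr2 (adjusted p = 0.387) and pr5 (adjusted p = 0.380) were lost, Hsf26 with adjusted p = 0.183.

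At 24h some defence genes had risen in every plot, and 5 of 20 heat shock genes were lower than at 0h. The gene pr5 (GRMZM2G402631, chromosome 1, 178035095 to 178036072), which encodes a thaumatin-like pathogenesis-related protein, went from 1.67 ± 2.71 to 126 ± 47.2 CPM (log2 change 6.20 ± 0.55, adjusted p = 4.46e-08). Genes of terpenoid phytoalexin synthesis rose too. They were an2 (GRMZM2G044481), an ent-copalyl diphosphate synthase gene, by 4.22 ± 0.43 (adjusted p = 3.78e-07), the cytochrome P450 gene CYP71Z16 (GRMZM2G067591) by 4.11 ± 0.35 (adjusted p = 2.19e-08), and TPS6 by 4.08 ± 0.28 (adjusted p = 9.36e-10). The small heat shock gene hsp18c (GRMZM2G034157) fell from 663 ± 270 to 105 ± 105 CPM (log2 change -2.66 ± 0.40, adjusted p = 9.67e-05, lower in 8 of 8 plots).

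Of the 6 genes in the pathogenesis-related list, 1 of which (GRMZM2G085678) is also in the ethylene list, 2 others rose at 24h (3 when adjusted over the list alone; camera adjusted p = 7.46e-07, estimated-correlation adjusted p = 0.0131). Of 27 glutathione S-transferase genes 7 rose and 0 fell (12 when adjusted over the list alone; adjusted p = 2.50e-10 and adjusted p = 0.0442 with an estimated correlation), among them gst24 (4.11 ± 0.44) and gst30 (1.47 ± 0.15). In the terpenoid list 3 of 12 genes rose and 1 fell (3 rose and 2 fell when adjusted over the list alone; adjusted p = 0.00100, estimated-correlation adjusted p = 0.0442). Its median was -0.17 while its mean was 0.85 and its test upward. Among 20 heat shock genes 5 fell and 0 rose (10 fell and 1 rose when adjusted over the list alone; adjusted p = 7.54e-07, but adjusted p = 0.142 with an estimated correlation), with hsp18f at -1.57 ± 0.35 and HSP70 at -1.21 ± 0.20. Of 9 benzoxazinoid genes 2 rose (6 when adjusted over the list alone; adjusted p = 2.64e-05, adjusted p = 0.0609 with an estimated correlation). Chitinase genes, too few to test as a list, included 3 of 4 that rose, such as GRMZM2G145461 (5.90 ± 0.36, adjusted p = 3.65e-10). Of the 3 clock genes measured, gigantea1 (GRMZM2G107101) was lower (39.6 ± 2.31 against 20.8 ± 3.67 CPM, log2 change -0.93 ± 0.11, adjusted p = 3.22e-06). When adjusted over the list alone 2 were lower. The endosperm cell wall invertase gene INCW2 (-0.99 ± 0.24, adjusted p = 0.0141) and the sucrose transporter gene sut1 (-0.89 ± 0.19, adjusted p = 0.00574) fell. The list of sugar transporters and invertases had 2 of 7 genes higher and 2 lower (2 and 3 when adjusted over the list alone; camera adjusted p = 0.367). The jasmonate synthesis list, with 3 of 23 genes higher, was not called with an estimated correlation (adjusted p = 0.142; 6 higher and 2 lower when adjusted over the list alone).

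At 3d, when fungal reads averaged 4.41%, many detoxification genes and some defence genes stood far above 0h, and the invertase gene INCW2 was lower. Among genes with an informative name that moved the same way in all plots, glutathione S-transferase genes led the rises. They were gst7 (GRMZM2G028556), from 0.195 ± 0.386 to 192 ± 136 CPM (log2 change 9.86 ± 0.80, adjusted p = 1.14e-08), gst8 (8.63 ± 0.65, adjusted p = 6.29e-09) and gst24 (8.30 ± 0.60, adjusted p = 4.31e-09). The gene ACO31, whose symbol stands for an ethylene-forming oxidase, rose by 8.24 ± 0.53 (adjusted p = 1.67e-09), and pr5 reached 378 ± 160 CPM (7.85 ± 0.69, adjusted p = 3.38e-08). INCW2 (GRMZM2G119689, chromosome 2, 57435843 to 57439124) fell from 62.0 ± 27.6 to 20.3 ± 11.4 CPM (-1.61 ± 0.35, adjusted p = 0.00274). Its list of sugar transporters and invertases went both ways, with 3 of 7 genes higher and 3 lower (3 and 3 when adjusted over the list alone; camera adjusted p = 0.670).

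Of 29 glutathione S-transferase genes 17 rose and 0 fell at 3d (17 when adjusted over the list alone; camera adjusted p = 5.42e-28, estimated-correlation adjusted p = 0.0160). Of 6 pathogenesis-related genes 4 rose (4 when adjusted over the list alone; adjusted p = 5.61e-06, estimated-correlation adjusted p = 0.0160). All 4 chitinase genes rose (4 when adjusted over the list alone), with GRMZM2G051943 going from 134 ± 94.9 to 2149 ± 549 CPM (4.01 ± 0.35, adjusted p = 3.31e-08). In the flavonoid list 4 of 7 rose (4 when adjusted over the list alone; adjusted p = 0.000302, adjusted p = 0.0971 with an estimated correlation), including the chalcone synthase gene C2 (4.41 ± 0.58) and the flavanone hydroxylase gene fht1 (4.90 ± 0.63). In the terpenoid list 4 of 13 rose (4 when adjusted over the list alone; adjusted p = 5.61e-06, adjusted p = 0.106 with an estimated correlation), including TPS6 (6.87 ± 0.46), CYP71Z16 (6.33 ± 0.46) and an2 (5.97 ± 0.52). The oxophytodienoate reductase genes opr1 (6.88 ± 0.61) and opr2 (3.84 ± 0.37) rose. They belong by symbol to the list of lipoxygenases and jasmonate synthesis, in which 7 of 24 genes rose and 1 fell. When adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.00111, adjusted p = 0.316 with an estimated correlation). Of 18 aleurone and transfer layer markers 5 fell, betl3 among them (-1.41 ± 0.29), and 1 rose (5 and 1 when adjusted over the list alone; adjusted p = 0.00226, adjusted p = 0.316 with an estimated correlation). The storage protein regulator gene o2 fell by 0.60 on the log2 scale, with an SE of 0.13 (adjusted p = 0.00363). Zein genes were mostly not called, with 1 of 24 higher and 1 lower (1 higher and 0 lower when adjusted over the list alone; adjusted p = 0.566).

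At 6d most zein genes were lower than at 0h, and some defence genes stood far above it. Of 24 zein genes, which encode the storage proteins of the endosperm, 20 fell and 0 rose. The gene gz27 (GRMZM2G138727) went from 32908 ± 6495 to 9733 ± 3391 CPM (log2 change -1.76 ± 0.26, adjusted p = 5.36e-06) and gz16 by a log2 change of -1.74 ± 0.25 (adjusted p = 4.96e-06). Sucrose synthase and starch genes fell as well, sus1 (GRMZM2G152908) from 903 ± 164 to 170 ± 31.9 CPM (-2.41 ± 0.16, adjusted p = 9.71e-11), sh1 by a log2 change of -1.23 ± 0.21 and the granule-bound starch synthase gene wx1 by -1.39 ± 0.25. TPS6 (chromosome 10, 55612816 to 55765958) rose from 3.19 ± 1.52 to 1283 ± 603 CPM (8.65 ± 0.40, adjusted p = 8.71e-13) and the chitinase gene GRMZM2G051943 from 186 ± 131 to 6341 ± 1470 CPM (5.09 ± 0.39, adjusted p = 5.09e-10). KSL4, a kaurene synthase-like gene, had 0 reads in the 8 libraries of 0h and 10.9 ± 6.49 CPM at 6d.

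Lists called at 6d against 0h were zeins (camera adjusted p = 0.000824), terpenoid synthesis with 10 of 12 higher and 2 lower (adjusted p = 0.000824), glutathione S-transferases with 15 of 28 higher and 7 lower (adjusted p = 0.00286) and starch synthesis with 8 of 13 lower and 1 higher (adjusted p = 0.0196). None of the 4 was called with an estimated correlation (adjusted p = 0.494 for each). Another of the 18 tested lists, the aleurone and transfer layer markers with 14 of 17 lower and 2 higher (adjusted p = 0.0637), was called only with plot as a block (adjusted p = 0.0143), and not with an estimated correlation (adjusted p = 0.512). The invertase genes incw1 (3.43 ± 0.21) and IVR1 (5.04 ± 0.47) rose while INCW2 fell (-3.32 ± 0.67), within a sugar transporter list of 4 higher and 1 lower of 7 (adjusted p = 0.147). The oleosin genes oleosin4 and OLE3 fell, the first by a log2 change of -2.24 ± 0.28 and the second by -2.17 ± 0.23. The dehydrin gene rab17 rose by 2.18 ± 0.23, and 5 of 17 embryo markers were higher and 6 lower (adjusted p = 0.879). In the phenylpropanoid list 3 of 9 were higher, such as the phenylalanine ammonia-lyase gene PAL1 (2.02 ± 0.27), and 6 lower, such as CCOAOMT2 (-1.74 ± 0.15), whose product acts in lignin synthesis (adjusted p of the list 0.0647).

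The remaining lists at 6d were not called. Higher and lower members numbered 4 and 2 of 6 for pathogenesis-related genes (adjusted p = 0.181), 7 and 10 of 23 for jasmonate synthesis (median log2 change 0.13, mean 0.19, test downward, adjusted p = 0.626), 8 and 5 of 20 for jasmonate ZIM-domain repressors, 3 and 1 of 6 for flavonoids and 2 and 2 of 9 for benzoxazinoids. They numbered 3 and 7 of 15 for WRKY factors, 7 and 16 of 30 for ethylene synthesis and response factors, 3 and 7 of 20 for heat shock genes, 1 and 5 of 7 for photosynthesis and 5 and 21 of 46 for ribosomal proteins. Lists too small to test had 3 and 0 of 4 chitinases, 1 and 1 of the 3 genes that the list of protease inhibitors caught, all by the symbol of ribosome-inactivating proteins (rip2 higher, rip1 lower), 0 and 3 of 3 class III peroxidases, 1 and 2 of 3 clock genes, 0 and 2 of 4 endosperm transcription factors, and 1 uncalled senescence gene. Counts adjusted over the list alone were the same for every list at 6d except that 17 ethylene genes were lower. With library totals the balance turned to more higher than lower members for jasmonate synthesis (11 and 6), WRKY factors (6 and 3), heat shock genes (9 and 1), embryo markers (9 and 4), endosperm transcription factors (1 and 0), clock genes (1 and 0) and ribosomal proteins (15 and 3), while zeins stayed at 15 lower and 1 higher.

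**Figure D3:**
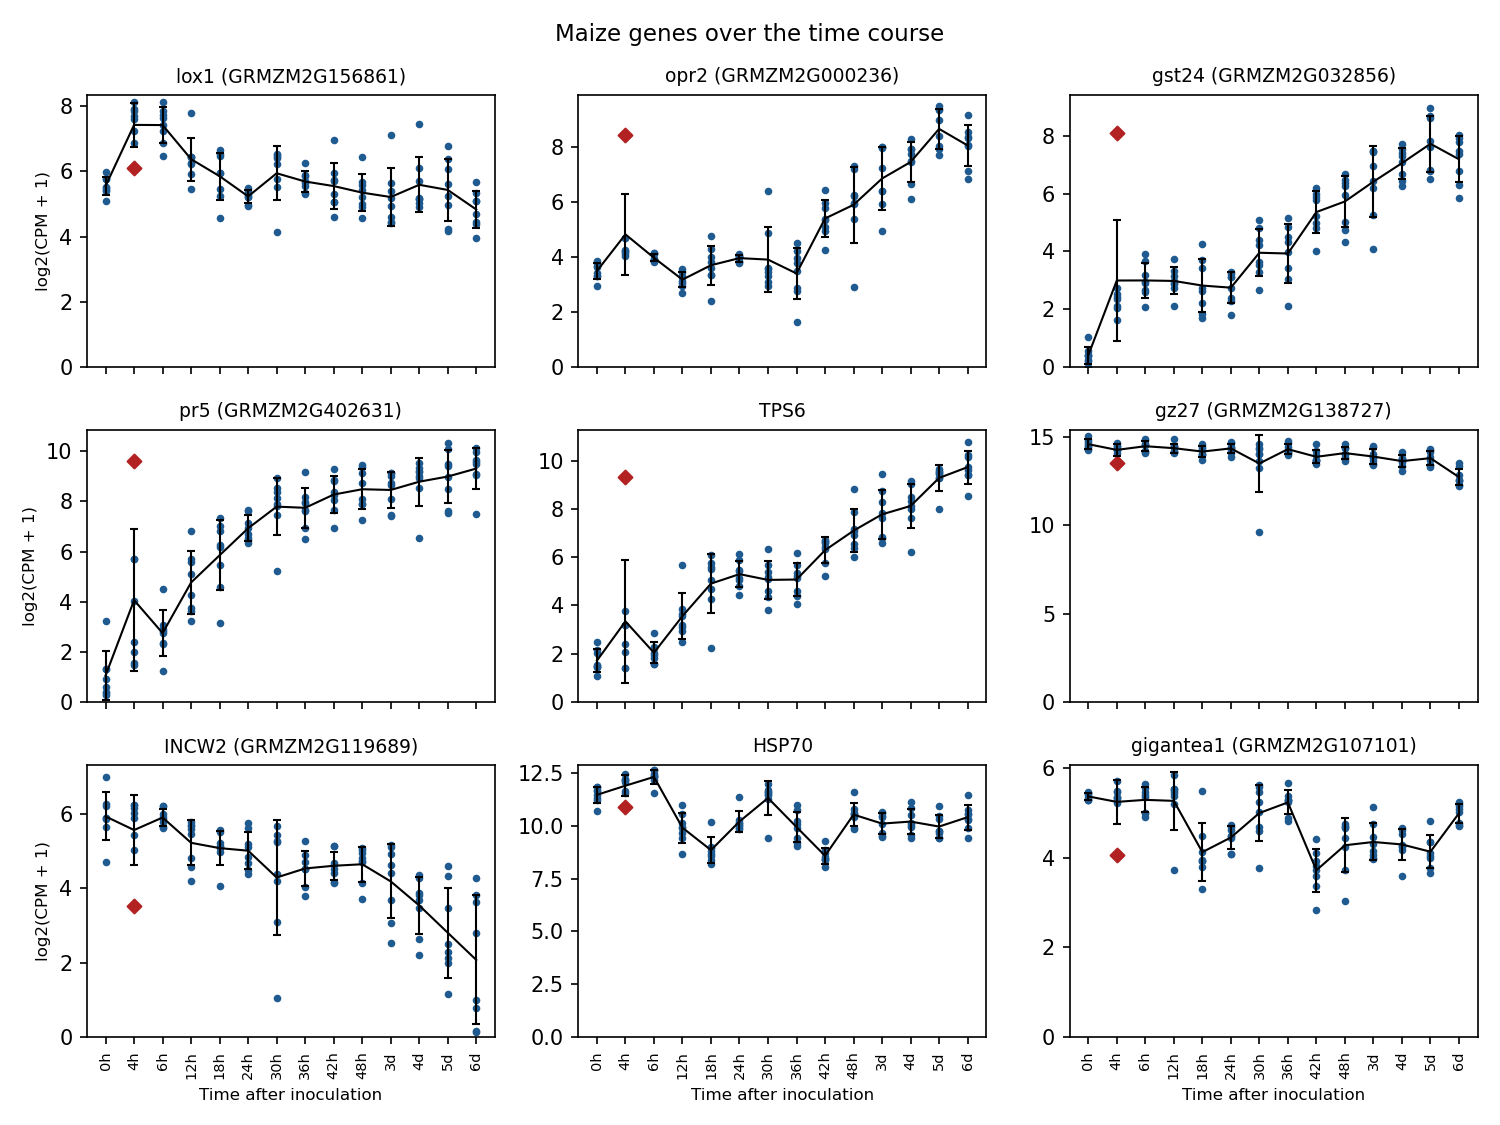
Normalised expression of 9 maize genes as log2(CPM + 1), scaled over all libraries, against time after inoculation. Points are single libraries, the red diamond is the library labelled 4h of plot 4, and lines with bars give the mean and SD of 8 libraries. The genes pr5, TPS6, gst24 and opr2 climbed to 6d or 5d, lox1 was highest at 4h and 6h, and HSP70 and gigantea1 went up and down.

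Between 3d and 6d, when the fungal share went from 4.41% to 40.1%, zein transcripts fell relative to other maize genes. The histone H2B gene his2b5 (GRMZM2G342515) was among the largest falls of genes with an informative name. It went from 118 ± 48.1 to 10.4 ± 4.68 CPM (log2 change -3.51 ± 0.31, adjusted p = 2.31e-07). Single genes that fell were the oleosin gene ole1 by a log2 change of -2.34 ± 0.45 (adjusted p = 0.000551), the zein gene gz16 by -1.40 ± 0.27 (adjusted p = 0.000556) and the gene for the endosperm ribosome-inactivating protein rip1 by -2.44 ± 0.36 (adjusted p = 3.75e-05). The isocitrate lyase gene ICL (GRMZM2G056369), of the glyoxylate cycle, rose from 115 ± 58.3 to 687 ± 278 CPM (2.57 ± 0.29, adjusted p = 2.55e-06), and an2 rose by 2.31 ± 0.36 (adjusted p = 6.65e-05).

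In all, 2886 maize genes were higher and 3731 lower at 6d than at 3d (6617 of 23261; 8129 without the libraries of low complexity, 6408 of them shared). Scaling mattered most here. With library totals the median log2 change of all genes went from 0.11 to 1.05 and 11672 genes were higher and 1040 lower, so the falls are falls relative to the median maize gene. With the preset correlation 11 lists were called, and none of them with an estimated correlation, where adjusted p = 0.452 for jasmonate synthesis and 0.400 for the other 10. Each list count that follows is to be read with that loss. Of 24 zein genes 17 fell and 0 rose (22 when adjusted over the list alone; camera adjusted p = 1.02e-07), and 2 fell and 0 rose with library totals. In the phenylpropanoid list 6 of 9 fell and 1 rose (6 and 1 when adjusted over the list alone; adjusted p = 0.00284), with comt at -1.36 ± 0.22 and BM1 at -1.52 ± 0.25, against 2 lower and 3 higher with library totals. Of 12 terpenoid genes 6 rose and 2 fell (8 and 2 when adjusted over the list alone; adjusted p = 0.0255), the only list of the 11 called whose test was upward. Of 29 glutathione S-transferase genes 10 fell and 2 rose (12 and 2 when adjusted over the list alone; adjusted p = 0.00366), which turned to 4 lower and 11 higher with library totals. The other 7 lists called went down. Of 23 jasmonate synthesis genes 8 fell and 1 rose (8 and 2 when adjusted over the list alone; adjusted p = 0.0255), of 15 WRKY genes 6 fell and 1 rose (6 and 2 when adjusted over the list alone; adjusted p = 0.0312), and of 30 ethylene genes 7 fell and 0 rose (7 when adjusted over the list alone; adjusted p = 0.0142). Of 45 ribosomal protein genes 15 fell and 0 rose (15 when adjusted over the list alone; adjusted p = 0.00720), of 13 starch genes 4 fell and 1 rose (4 and 1 when adjusted over the list alone; adjusted p = 0.0135), of 16 aleurone and transfer layer markers 3 fell and 1 rose (3 and 1 when adjusted over the list alone; adjusted p = 0.0103), and of 7 photosynthesis genes 2 fell and 0 rose (4 when adjusted over the list alone; adjusted p = 0.0218). With library totals more members were higher than lower for jasmonate synthesis (11 and 3), WRKY genes (5 and 1), ethylene genes (13 and 4), ribosomal proteins (17 and 1), starch (5 and 2) and aleurone markers (2 and 1), and 0 photosynthesis genes were called. Pathogenesis-related genes were not called as a list (3 higher and 1 lower of 6, or 3 and 2 when adjusted over the list alone; adjusted p = 0.934). The embryo markers, which hold the oleosin genes, were not called either (3 higher and 7 lower of 17, the same when adjusted over the list alone; adjusted p = 0.273, and adjusted p = 0.630 with an estimated correlation).

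For the fungus, the comparisons asked how its own transcripts changed as it spread. Between 36h, the first time with enough fungal reads, and 6d, 2567 of 7583 fungal genes were higher and 319 lower, on a scale where the median fungal gene was higher by 0.83 (log2). With plot as a block 2752 were higher and 102 lower and the median was 1.95, and the lower genes numbered 563 by DESeq2 (2728 higher), 423 with median-ratio factors (2255 higher) and 499 with only the libraries that hold enough fungal reads (3575 higher). The number of lower genes therefore depends on the method. The gene AFLA_063290 had 0 reads in the 8 libraries of 36h and 5528 in those of 6d (adjusted p = 0.000158). The gene AFLA_023030 fell from 2267 ± 3456 to 18.8 ± 14.9 CPM (log2 change -6.91 ± 0.77, adjusted p = 4.67e-06, 8 of 8 plots). Of the 30 genes of the aflatoxin cluster 17 were lower and 2 higher (18 and 2 when adjusted over the list alone; camera adjusted p = 1.20e-16, adjusted p = 0.0403 with an estimated correlation), with a median log2 change of -1.80. Plots differed, as members called lower ranged from 8 of 8 plots lower (AFLA_139220) to 4 of 8 (AFLA_139280). Levels at 36h were widely spread, such as 2716 ± 2910 CPM for AFLA_139190.

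Between 3d and 6d the aflatoxin cluster fell as a group. Of its 30 genes 26 were lower and 0 higher (28 when adjusted over the list alone), with a median log2 change of -3.22 (camera adjusted p = 2.13e-63, adjusted p = 0.00118 with an estimated correlation). AFLA_139390 fell from 3946 ± 2424 to 166 ± 90.4 CPM (-4.57 ± 0.48, adjusted p = 5.56e-06, lower in 8 of 8 plots), while AFLA_101840, outside the cluster, had 0 reads at 3d and 47.4 ± 48.8 CPM at 6d. The cluster took 1.95% ± 1.60 of the fungal reads at 36h, 2.14% ± 1.00 at 42h, 2.03% ± 0.655 at 48h, 3.82% ± 1.48 at 3d, 3.91% ± 0.805 at 4d, 3.36% ± 0.823 at 5d and 0.482% ± 0.243 at 6d (n = 8 each). In all, 325 of 8842 fungal genes were higher and 469 lower at 6d than at 3d. This count depended on the method, with 852 higher and 661 lower by DESeq2, 1602 calls without a filter and 1182 (654 higher, 528 lower; 755 shared) without the libraries of low complexity. With plot as a block 438 were higher and 336 lower.

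**Figure D4:**
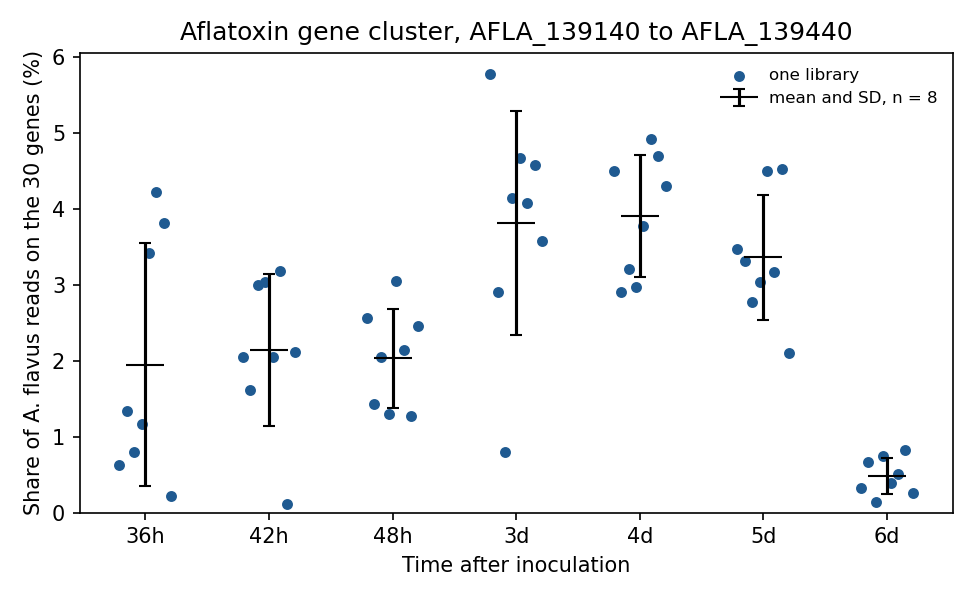
Share of A. flavus reads on the 30 genes of the aflatoxin cluster (percent) against time from 36h to 6d, with 1 point per library and the mean and SD of 8 libraries. The means lay at 3.82% at 3d and 0.482% at 6d.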

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

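Over 7 measures, 14 of the 91 groups of libraries tested held 1 library far from the others, by Dixon's 95% limit on its gap to the nearest library. Chance gives about 1 in 20 where values are spread normally. Untransformed values were used, and some, such as the fungal share, are skewed, so the 14 is not to be read against that rate. All tests of the library labelled 4h of plot 4 were written after it had been seen, except that of a mixture.

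Total reads were low in plot 8 at 0h (17736180, others 26503647 to 31215528), at 6h (10696902, others from 25092948) and at 42h (12708110, others from 25598594). The A. flavus share stood apart at 24h in plot 7 (0.238%, others at most 0.0492%), at 48h in plot 8 (5.95%, others at most 1.39%) and at 4h in plot 4 (12.5%, others at most 0.0126%). The feature GRMZM2G006937 took 48.9% of the maize reads at 6d in plot 2, against 7.22% to 19.4% in the other 7 libraries. Zein genes took 22.2% of the other maize reads at 4h in plot 5 (others at most 13.6%), 17.6% at 12h in plot 6 (others at most 14.5%) and 14.9% at 4d in plot 7 (others at most 11.2%). Organelle genes took 2.17% of maize reads at 30h in plot 7 (others at most 0.133%), 0.223% at 48h in plot 4 (others at most 0.116%) and 0.202% at 6d in plot 2 (others at most 0.0975%). The 30h library of plot 7 also had zein genes at only 0.899% of its other maize reads (others 6.66% to 14.9%), a gap within the limit. Its maize profile correlated by 0.745 with the median of the other 30h libraries. At 3d the library of plot 6 had 18427 maize genes detected, against 24591 to 29495 in the others. No explanation of these was tested beyond that of the library below.

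The library labelled 4h of plot 4 held 12.5% A. flavus reads, and on a scale where 0 is the other 4h libraries and 1 the 5d libraries, the 3004 maize genes that rose over 2-fold at 5d had a median of 0.93 in it and the 2253 that fell had 0.58. These lie near the 0.92 and 0.58 of the 4d library of plot 4 and the 0.85 and 0.61 of the 3d library of plot 2. The 5d libraries had 0.80 to 1.13 for the genes that fell. By its whole maize profile the library was nearest to 5d (correlation 0.928 with the 5d median, 0.850 with that of the other 4h libraries). Its closest single library was that of 5d in plot 8 (correlation 0.910), so these values do not settle on 1 late time. A swap with a late library of plot 4 is argued against by the lowest fungal share among its 3d to 6d libraries, 4.79%, far above the 0.0126% of the highest other 4h library. A whole library of a later time under this label may explain it, as 0.58 lies within the 0.28 to 1.13 of the 4d and 5d libraries. A mixture with late RNA cannot be told apart, because the bounds of 0.5 and 0.7 for the ratio of the 2 positions (here 0.627) did not separate it from unmixed 4d libraries, and an ear of plot 4 colonised by 4h stays open, since the risen genes at 0.93 would look the same.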

How the results depend on the processing

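Of the counts of genes under alternatives, 138 stayed within 1.5 times the reported count and 37 did not, and of the counts of lists 13 did and 5 did not. Of the values of named genes 3237 kept their direction and side of the threshold, 196 lost the call and 5 reversed, and of the values of single lists 197, 37 and 4, with 1 that became called. Leaving out GRMZM2G006937, the library labelled 4h of plot 4 or libraries with few genes detected was chosen after the data were seen. The cause was not tested except where named.

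DESeq2 called 355 genes at 4h, 954 at 6h, 2412 at 30h, 1993 at 48h and 1513 fungal genes for 6d against 3d. With plot as a block the counts were 92 at 4h, 883 at 30h, 693 at 48h and 1855 at 3d. All libraries in 1 fit gave 485 at 4h, 130 at 6h, 689 at 12h, 974 at 18h, 327 at 24h and 1704 at 36h. Without plot 7, with fewer libraries, there were 120 at 4h and 817 at 24h. Library totals gave 1130 at 12h, 1186 at 18h, 582 at 24h, 769 at 30h, 1672 at 42h, 666 at 48h and 12712 for 6d against 3d. A 2-fold minimum, which can only lower a count, gave 242 at 6h, 734 at 12h, 942 at 18h, 392 at 24h, 708 at 30h, 1303 at 36h, 1432 at 42h, 1541 at 3d, 2267 at 4d, 5257 at 5d, 7872 at 6d and 4273 for 6d against 3d. No filter, with more genes tested, gave 1602 fungal genes for 6d against 3d.

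With an estimated correlation 1 list was called at 4h, 3 at 24h, 2 at 3d, 0 at 6d and 0 for 6d against 3d. Without the doubted libraries the tests of 4 uncalled lists changed direction, at 4h jasmonate ZIM-domain repressors (adjusted p = 0.745) and WRKY factors (0.918), and for 6d against 3d pathogenesis-related genes (0.952) and flavonoids (0.899). Library totals, which move the median of all genes up, reversed gigz1b (0.24) and gigantea1 (0.36) at 6d, and GRMZM2G005633 (0.14), BX8 (0.24) and vpp1 (0.21) for 6d against 3d.

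The A. flavus share at 6h was no longer below 0h untransformed (-0.00403 percentage points). Counting only fungal genes with no reads at 0h gave log2 differences of 5.65 at 4h, 3.56 at 6h and 5.05 at 12h, a rise that follows from choosing genes at 0 in 0h. Uniquely placed reads gave 0.00977 at 12h, and leaving out the library of plot 4 gave -0.44 at 4h. Low fungal depth before 36h kept fungal genes from being tested there.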

Other observations

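Tests of the daily rhythm, of lanes, of libraries with few genes detected and of the scaling of fungal counts were written after the patterns had been seen; those of fungal depth, of the chromosome region and of other splits were written before.

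The heat shock gene HSP70 and the clock gene gigantea1 went up and down over the first 2 days. HSP70 averaged 2941 ± 705 CPM at 0h, 5269 ± 1093 at 6h, 509 ± 282 at 18h, 2834 ± 981 at 30h and 396 ± 110 at 42h (n = 8 each). The gene gigantea1 averaged 40.4 ± 2.24 CPM at 0h, 21.2 ± 3.67 at 24h, 37.3 ± 7.01 at 36h and 12.8 ± 4.31 at 42h. Both genes were lower at 24h than at 0h, although these times lie a day apart. A daily rhythm alone therefore does not account for them.

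Maize libraries of 12h and 36h shared a profile apart from those of 24h and 48h. Over 28815 genes the difference of 12h and 24h correlated by 0.395 with that of 36h and 48h, which restates the pattern. Lanes as the whole cause are argued against by the design, since within each plot 12h and 24h shared a lane and so did 36h and 48h. Without the libraries with few maize genes detected the correlation was 0.352. A daily rhythm of the kernel may explain it, but the correlations below do not tell it apart from a steady trend with time. The differences of 6h and 18h and of 30h and 42h, in other libraries, correlated by 0.430 (highest of 1000 shuffles 0.379). Each difference sets a time against one 12h later, so a steady trend would give a positive correlation too. The same holds for the correlation of 0.395. On the third principal component, an axis of shared variation over 24714 maize genes, the mean was -40.7 ± 9.58 (SD) at 6h. It was 26.7 ± 16.1 at 18h, -17.9 ± 18.5 at 30h and 44.2 ± 9.41 at 42h. Along this axis, with 4.18% of the variance, the fall from 18h to 30h argues against a steady trend as the whole cause. At 12h, 24h, 36h and 48h the means were 9.89, 8.23, 18.9 and 9.71, within their spread, so a trend stays open there. Hour of sampling is not in the tables, and temperature or handling at set hours stays open as untested.

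The aflatoxin cluster was lower at 6d than at 3d, with a median log2 change of -3.22. Scaling is argued against by its share of fungal reads, which was lower at 6d in 8 of 8 plots, and unequal depth by a median of -3.14 after the 6d reads were thinned to those of 3d. A change of the whole chromosome region is argued against by the neighbours' median of -0.038, but this rests on the 30 genes on the left (0.05), while the 7 genes on the right, up to the end of the contig, had -1.46. The cluster genes next to the right edge, AFLA_139420, AFLA_139430 and AFLA_139440, had log2 changes of -0.74, -0.46 and -0.07. None of these was called lower over all fungal genes, so the fall was not seen to run unbroken across that edge. A fall of genes past it stays open. A change in the fungus with time, which the design names, may explain the pattern and was not tested apart from these.

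Other splits of the same libraries were counted for each gene result, 100 splits with the real one included. In every comparison of 2 times 1 of 100, the real one, gave as many calls. Chance is thus unlikely for each but not excluded, since 1 of 100 is the smallest share these splits can give. Against 0h the real count and the highest other were 217 and 20 at 4h, 568 and 65 at 6h, 2008 and 529 at 12h, 2144 and 1085 at 18h, 1260 and 101 at 24h, 1436 and 53 at 30h, and 3779 and 3193 at 36h. They were 3110 and 1214 at 42h, 1304 and 13 at 48h, 2940 and 258 at 3d, 4683 and 2080 at 4d, 10678 and 6496 at 5d and 13926 and 9922 at 6d, and for 6d against 3d 6617 and 5146. For fungal genes they were 2886 and 367 for 6d against 36h and 794 and 107 for 6d against 3d. Of the splits that part all 8 plots, as the real one does, 1 again gave as many in each comparison. Many of those splits exchanged the 2 libraries of some plots only and could keep much of the real contrast. The highest other is therefore not a chance level. Among splits that part fewer plots the highest was 0 at 36h, 3053 at 5d and 0 at 6d. For the whole course, 1 of 24 splits, the real one, gave 14108 calls, and the highest other gave 499.

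Counts of lists called with camera's preset correlation were another matter. At 4h 10 lists were called, and 3 of 100 splits gave as many (highest other 10), but these 3 were among the 52 splits that part all 8 plots as the real one does, a share over 0.05, so chance is not excluded there. For 6d against 3d 11 lists were called, and 2 of 100 splits gave as many (highest other 11). Both were among the 52 splits that part all 8 plots. Chance is unlikely for that count but not excluded, as a split other than the real one reached it. No single list was called with an estimated correlation. As many lists came up more often at 24h (8 lists, 8 of 100 splits, highest other 10), 3d (8 lists, 17 of 100 splits, highest other 10) and 6d (4 lists, 37 of 100 splits, highest other 8). Chance stays open at these times. The aflatoxin cluster alone was called in 84 of 100 splits for 6d against 36h and in 79 of 100 for 6d against 3d, so its preset p excludes nothing and the p with an estimated correlation is the one to read.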
